A study of Arabidopsis thaliana with 2 samples.

How the data were processed

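The series holds 2 RNA-seq libraries of Arabidopsis thaliana, 1 from wild-type Columbia (Col) seedlings and 1 from an ARF18 overexpression line. Per the labels' protocols, RNA was extracted with Trizol from whole seedlings, first-strand cDNA was made with random primers, and the libraries were sequenced on an Illumina HiSeq or other sequencer. The labels give the age as 7 days in one place and in another describe 4 days in the dark followed by 7 days in white light, so the age at harvest was left open. Strandedness, aligner and counting program are not given in the sources used here. The genome build was TAIR 10, per the submitters' processing notes.

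The authors deposited raw read counts per transcript model and RPKM values (reads scaled to transcript length and to the counted reads of the library). The deposited RPKM values were recomputed from the counts, the transcript length in the table and the sum of the count column, and differed by at most 3e-06 percent. A count of 0 is written by the authors as an RPKM of 0.01, and was set to 0 here. The authors' log2 ratio in the deposited table is that of the RPKM columns, within 6e-08. The deposited p-value and FDR columns come from a test on the reads of the 2 libraries, which the sources used here do not name, so it compares those libraries and not the genotypes.

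The table has 24295 transcript models of 21825 loci, each with at least 1 read in 1 of the libraries. Counts and RPKM were summed per locus. The 2226 loci with more than 1 model had a median summed count of 23, against 100 for loci with 1 model, so levels of loci with several models may be understated. Gene symbols, gene classes and transcript sequences came from a TAIR 10.1 reference annotation, which held 21649 of the loci. The library totals were 7059226 counts in wild type and 6824188 in the overexpression line.

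With 1 library per genotype there was no test between genotypes and no replicate check. The main measure was log2 of (RPKM + 1) in the overexpression over the wild-type library, which understates the difference of low genes. It was taken for nuclear genes with a mean RPKM of 1 or more. Genes at least 2-fold apart on this scale were counted. Count ratios, normalised to the library totals, carry 95% exact conditional binomial intervals, which cover counting error only. Where one library had 0 counts, a floor of 3 counts in that library gave a bound. The 32 gene lists were fixed before the data were examined, as were the rule for named genes and most of the alternative settings. No listed locus was left out for a contradicting name. The reference had no symbol for 13 of the 759 entries, and 3 were written under a synonym. For lists with 5 or more members, the median has an exact order-statistic 95% interval and a percentile among 10000 random lists matched on mean RPKM in 20 bins, as a description of these libraries. ARF18 was left out of the ARF family list. Genes named in the text are ARF18, the 12 highest and 12 lowest ratios among genes at least 2-fold apart with a mean RPKM of 5 or more, and up to 4 members per list with the largest absolute log2 ratio. Others are marked as chosen after their values were seen.

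Alternatives chosen then were pseudocounts of 0.1 and 5 RPKM, median-centred rescaling, trimmed mean of M values (TMM) scaling, counts scaled to the library total (CPM), other filters and thresholds, a counting interval that excludes 1, organelle genes included, and the authors' own calls. Adjustment for transcript length and GC content, and loci with 1 transcript model, were added after seeing the data. The adjustment subtracted the median log2 ratio of 50 bins of transcript length, then of 50 bins of GC content. GC content was known for 15069 of 15083 expressed genes.

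The steps were tested on simulated counts for the comparison of the overexpression with the wild-type library, with 15083 genes of which 200 were changed. Of 25 genes each made 4-fold higher and 4-fold lower, 100% and 92% passed the 2-fold threshold. For 3-fold the shares were 92% and 88%, for 2-fold 32% and 24%, and for 1.5-fold 0%. Among 14883 unchanged genes, 24 passed as higher and 43 as lower by counting error alone. The simulated counts held no trend with transcript length, unlike the data. The work used Python, numpy, pandas, scipy, matplotlib and biopython (versions 3.11.15, 2.4.6, 2.3.3, 1.17.1, 3.10.9 and 1.88).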

Results

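RNA from whole seedlings of wild-type Arabidopsis (Columbia) and of a line overexpressing ARF18, a member of the auxin response factor family of transcription factors, was sequenced as 1 library each. The wild-type library held 7059226 counted reads and the overexpression library 6824188. The comparison asks how transcript levels differ between a plant line made to overexpress ARF18 and its wild type. Because each genotype had 1 library, values below describe these 2 libraries. Intervals of count ratios and of shares of counts cover counting error only. Those of list medians describe the spread between member genes, and neither kind covers the spread between plants.

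ARF18 itself was higher in the overexpression library, at 472 counts against 97, or an RPKM of 29.5 against 5.85. The count ratio was 5.03 (95% exact conditional binomial interval 4.04 to 6.33), and the log2 ratio with a pseudocount was 2.15. In the TAIR 10.1 annotation, ARF18 (AT3G61830) lies on the plus strand of chromosome 3 from 22887889 to 22891455, with annotated transcripts of 12 and 13 exons. In the authors' deposited table its log2 ratio was 2.33 at an FDR of 8.7e-61. A small annotated gene whose end lies 567 bp before the ARF18 start, AT3G61829 (chosen after its values were seen), had 0 counts in wild type and 6 in the overexpression library, at least 2.07-fold higher against a floor of 3 counts in the wild-type library, with a lower limit of the exact interval of the ratio of 1.22.

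The other ARF genes showed no comparable difference. Of 8 further family members with a mean RPKM of 1 or more, none was 2-fold apart, and their median log2 ratio was -0.06 (-0.53 to 0.25; percentile 32.8), or 0.17 (percentile 93.7) adjusted for transcript length and GC content as described below. ARF10 had a count ratio of 0.663 (0.498 to 0.879) and ARF19, an activating ARF of root auxin response, 0.564 (0.365 to 0.859). ARF5, known for its role in embryo and vascular patterning, had 0.899 (0.778 to 1.04) and ARF17 1.26 (0.818 to 1.96). The log2 ratio of ARF19 was -0.53, or -0.20 adjusted, and that of ARF5 turned from -0.15 to 0.13.

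Across 15083 expressed nuclear genes, 188 were at least 2-fold higher and 100 at least 2-fold lower in the overexpression library. Genes higher included many short transcripts and several genes of a lipid-transfer or 2S albumin-like protein family, and genes lower were led by AT4G29200 and extensin-like cell wall proteins. The median log2 ratio was 0.03 and its SD across genes 0.40. In the authors' deposited table, 181 transcript models were at least 2-fold higher and 185 at least 2-fold lower at an FDR of 0.05 or less. In the authors' deposited table, loci called in this way included 106 of the genes higher and 73 of the genes lower by size.

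Among the 12 named genes with the highest ratios, 4 belonged to the lipid-transfer and 2S albumin-like family. AT5G46900 had 1041 counts against 371, a ratio of 2.90 (2.58 to 3.28). AT4G12510 had 247 against 85, a ratio of 3.01 (2.34 to 3.89), and AT4G12545 79 against 21, a ratio of 3.89 (2.38 to 6.63). AIR1, named for its induction by auxin in root cultures, had 38 against 11, a ratio of 3.57 (1.79 to 7.75). These genes have close relatives with which reads may be shared, so single values within the family are uncertain. The transcribed pseudogene AT1G69140 had a ratio of 4.27 (2.71 to 6.97), and the GPI19/PIG-P subunit gene AT2G39445 4.03 (1.98 to 9.06). The non-coding RNA genes AT1G04425 and AT3G61118 had ratios of 4.03 (1.98 to 9.06) and 3.1 (1.66 to 6.15), and the uncharacterised AT4G39675 3.57 (1.79 to 7.75). The snoRNA genes AT1G75166, with 7 counts against 1, and AT2G35744, with 5 against 1, had intervals that included 1.

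The gene with the lowest ratio, AT4G29200, a beta-galactosidase related gene, had 746 counts in wild type and 0 in the overexpression library. Against a floor of 3 counts in that library it was at least 240-fold lower, and the upper limit of the exact interval of the ratio was 0.00513. The nearby genes OZF2 (363 and 317 counts) and PFK1 (493 and 455), chosen after their values were seen, had ratios of 0.903 and 0.955, and GGT4 (8 and 12) 1.55 (0.583 to 4.38). Whether the line carries an insertion, a deletion or another background difference at AT4G29200 was not tested, so the value need not be a response to ARF18. Leucine-rich repeat extensins, cell wall proteins of growing cells, followed: the gene annotated as number 4 of the family, AT3G24480, had 214 counts against 2355, or 10.6-fold lower (interval of the ratio 0.0813 to 0.108). AT4G18670 was 5.69-fold lower and LRX3 5.57-fold lower. The proline-rich genes AT2G43150 (14844 against 60289 counts), AT1G23720 and AT3G28550 were 3.93-fold, 4.03-fold and 3.47-fold lower. Random lists of other genes near to such genes in C-rich sequence also had a negative median, -0.41 after adjustment for length and GC content. Few other genes were as C-rich as the most C-rich of these genes, so the match was incomplete. OCT1, an organic cation and carnitine transporter, had 61 counts against 252, a ratio of 0.250 (0.186 to 0.332). AT3G23450, the pseudogene AT5G38870 and the long non-coding RNA gene AT3G22121 had ratios of 0.266, 0.234 and 0.243. The snoRNA gene AT3G47342 had 1 count against 5, with an interval that included 1.

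**Figure D1:**
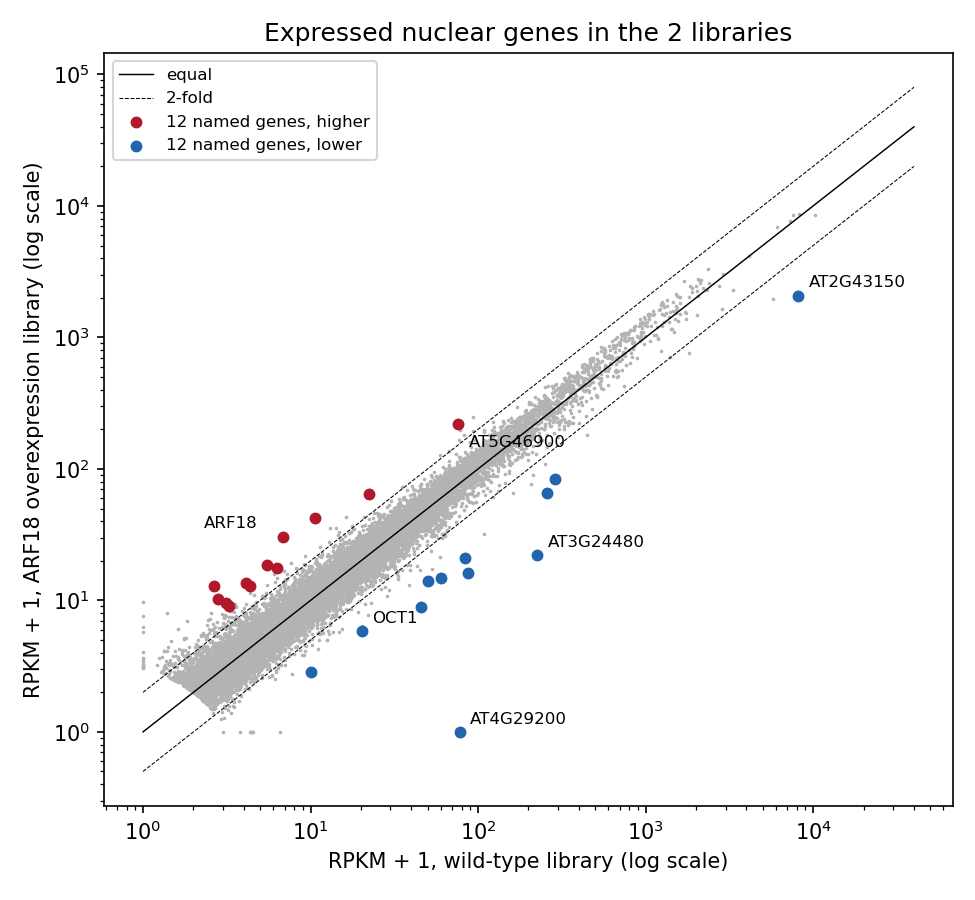
RPKM + 1 of each expressed nuclear gene in the wild-type library (x axis) and the overexpression library (y axis), both on log scales. Grey points are genes, coloured points the 12 named genes in each direction, and dashed lines mark 2-fold; ARF18 lies at 5.85 and 29.5 RPKM, and AT4G29200 at 76.9 and 0.

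The log2 ratio differed with transcript length across genes, which are not independent replicates. Spearman's rho was -0.52 with length and -0.18 with GC content. Among genes with a mean RPKM of 5 or more, the median log2 ratio was 0.36 in the shortest of 10 equal groups by length (up to 680 bases) and -0.36 in the longest (2502 bases or more). The genes at least 2-fold higher had a median length of 616.5 bases, against 1415 for all expressed genes. After adjustment for length and GC content, an alternative chosen after seeing the data, 79 genes were 2-fold higher and 131 lower. Of these, 77 higher and 77 lower were also 2-fold apart before adjustment. The share of higher genes among those 2-fold apart was 65.3% as deposited and 37.6% adjusted. ARF18 had an adjusted log2 ratio of 2.29.

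**Figure D2:**
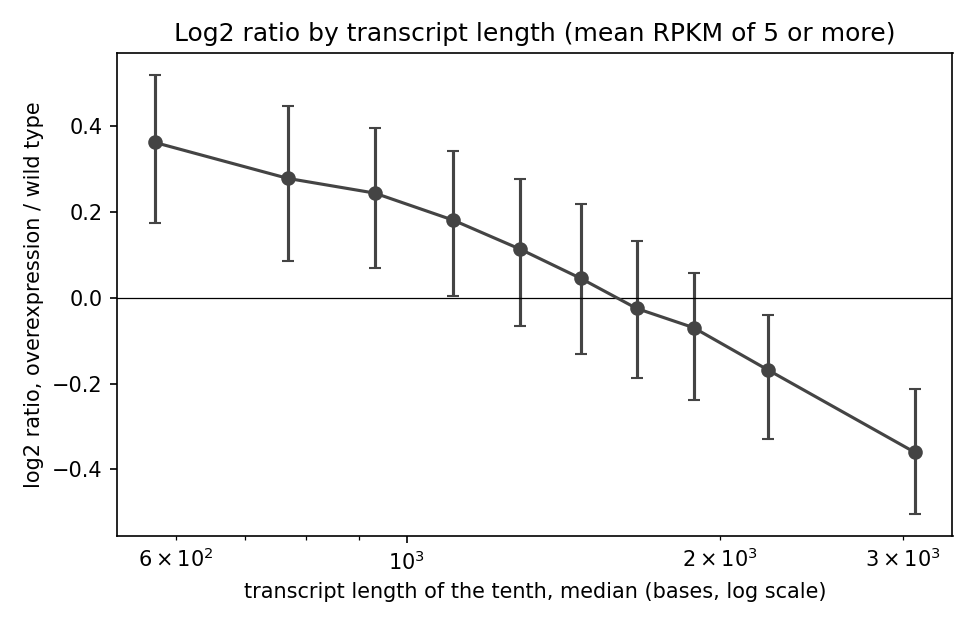
Log2 ratio of the overexpression over the wild-type library (y axis) in 10 equal groups of genes by transcript length in bases (x axis, log scale), for genes with a mean RPKM of 5 or more. Points are medians and bars the quartiles; the median is 0.36 in the shortest group and -0.36 in the longest.

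Genes of phosphate starvation stood lowest among the lists. Of 14 expressed members, 12 had negative log2 ratios and 10 had counting intervals wholly below 1. Such interval counts, here and for the lists below, are not adjusted for length and depend on the number of reads. Their share over all expressed genes was not taken, and 8 of 12 reference genes also had intervals above 1, so they only describe members. The median log2 ratio of the phosphate list was -0.54 (-0.72 to -0.19), below nearly all matched random lists (percentile 0.00). It was -0.57 (percentile 0.00) adjusted for length and GC content. PS2, a phosphatase gene induced by phosphate starvation, had 89 counts against 211, a ratio of 0.436 (0.337 to 0.562). The non-coding RNA gene IPS1 had 0.553 (0.390 to 0.777), SQD1, of sulfolipid synthesis, 0.608 (0.536 to 0.688), and SPX3 4 counts against 11, a ratio of 0.376 (0.0874 to 1.27).

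Flavonoid and anthocyanin genes were also lower in the overexpression library. Of 18 expressed members, 17 had negative log2 ratios, 9 with counting intervals wholly below 1, and none was 2-fold apart. The median was -0.29 (-0.55 to -0.17; percentile 0.02) and -0.42 (percentile 0.00) adjusted. DFR, dihydroflavonol reductase, had a ratio of 0.531 (0.428 to 0.657), UGT75C1 0.606 (0.498 to 0.736), UF3GT 0.631 (0.479 to 0.826), and PAL2, at the entry to phenylpropanoid synthesis, 0.626 (0.589 to 0.666).

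Root marker genes and cell wall loosening genes stood at the other end. Of 20 root markers, 14 had positive log2 ratios, with a median of 0.38 (-0.0021 to 0.65; percentile 100) that was 0.18 (percentile 99.7) adjusted. The aquaporin TIP2;3 had a ratio of 2.74 (1.96 to 3.89), the quiescent centre gene WOX5 2.59 (1.42 to 4.95) and WER 3.1 (1.07 to 10.9), whereas the root hair gene LRX1 had 0.389 (0.319 to 0.473). Of 26 expansin and XTH genes, 17 had counting intervals above 1 and 2 below, with a median of 0.33 (0.13 to 0.65; percentile 99.9) and 0.14 (percentile 98.9) adjusted. XTH17 had a ratio of 2.32 (1.67 to 3.27), EXPA5 3.88 (1.74 to 9.79), EXPA3 1.87 (1.57 to 2.23) and XTH33 2.51 (0.990 to 7.17). The root and expansin lists share EXPA7 and EXPA18, named here for the overlap. Of the root markers, 10 had counting intervals above 1 and 4 below. After adjustment for length and GC content 6 lay above and 3 below, and WER was not among these 6.

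**Figure D3:**
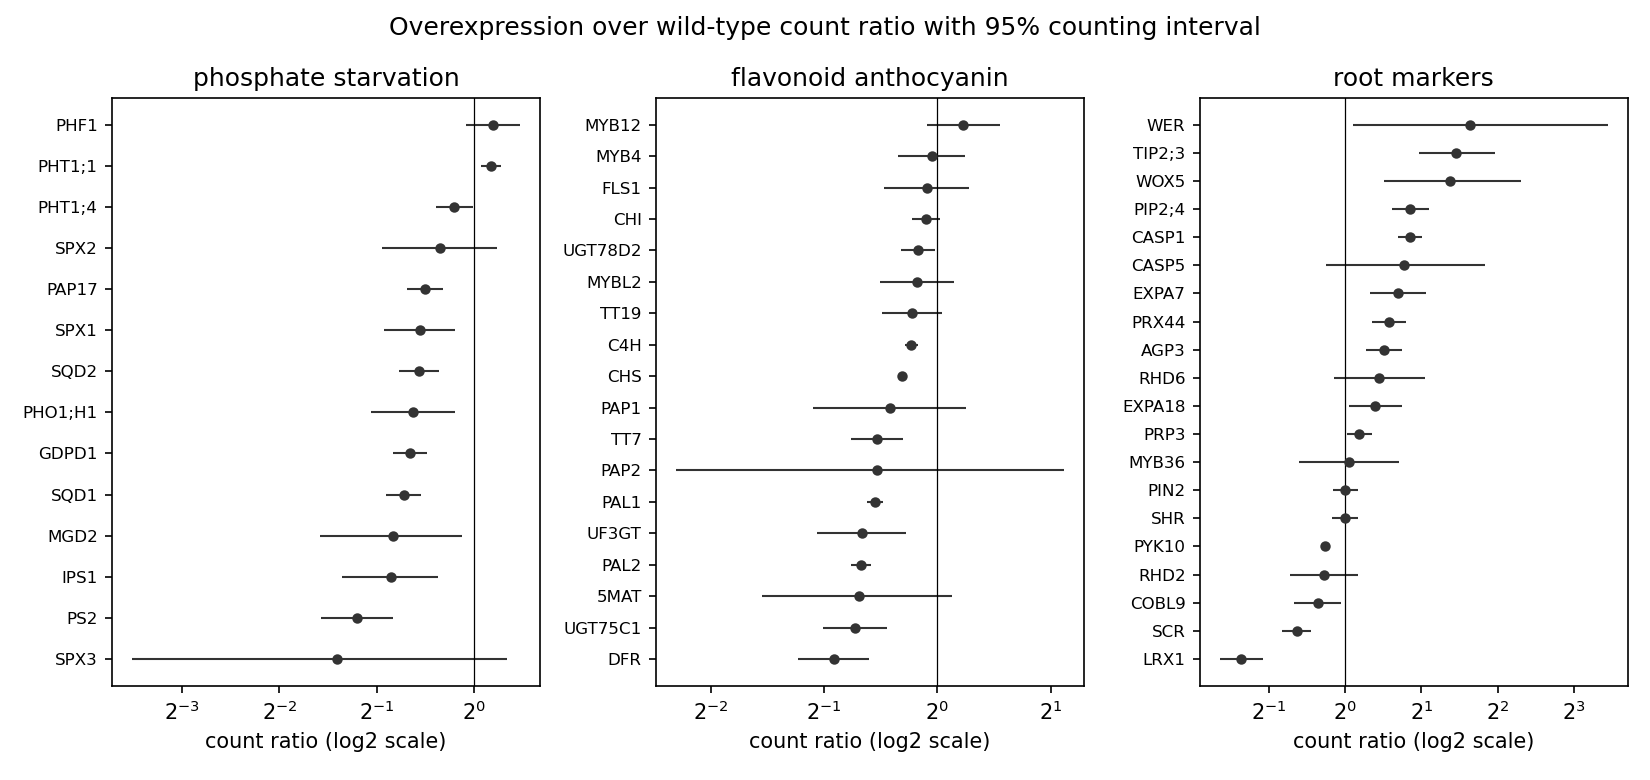
Count ratio of the overexpression over the wild-type library (x axis, log2 scale) for members of the phosphate starvation, flavonoid and root marker lists. Bars are 95% exact conditional binomial intervals; 12 of 14 phosphate and 17 of 18 flavonoid members have negative log2 ratios, and 14 of 20 root markers positive ones.

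Jasmonate and cell cycle lists had medians above nearly all matched random lists. Of 14 jasmonate genes, 3 had counting intervals above 1 and 2 below. They had a median of 0.29 (-0.24 to 0.56; percentile 98.9), or 0.21 (percentile 99.1) adjusted, with ORA59 at a ratio of 1.85 (1.59 to 2.17) and PR4 at 1.49 (1.43 to 1.55). The log2 ratio of ORA59 was 0.87, or 0.64 adjusted, and that of PR4 0.57, or 0.31 adjusted. JAZ5 and JAZ9 had intervals that included 1. Of 26 cell cycle genes, 7 had counting intervals above 1 and 1 below, with a median of 0.20 (0.04 to 0.28; percentile 97.6), or 0.14 (percentile 99.2) adjusted. The mitotic kinase gene AUR1 had a ratio of 1.66 (1.3 to 2.14), CDC20.1 1.37 (1.1 to 1.70), CYCB1;2 1.37 (1.08 to 1.73) and CYCD1;1 0.708 (0.579 to 0.863).

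Auxin response genes, the class most often tied to ARFs, did not stand apart. The 25 Aux/IAA and GH3 genes had a median of 0.03 (-0.16 to 0.28; percentile 49.0), or -0.0044 (percentile 47.5) adjusted, with none 2-fold apart. IAA17 had 1098 counts against 848, a ratio of 1.34 (1.22 to 1.47), while IAA10, IAA12 and GH3.9 had intervals that included 1. The log2 ratio of IAA17 was 0.42, or 0.26 adjusted. The 13 SAUR genes had a median of 0.22 (percentile 95.4) that was -0.07 (percentile 23.3) adjusted, and 4 had counting intervals above 1 and none below. Of the named members SAUR19, SAUR24, SAUR51 and SAUR52, only SAUR52 had an interval above 1, at 1.75 (1.08 to 2.87). Its log2 ratio was 0.69, or 0.40 adjusted. Auxin synthesis, transport and perception genes had a median of -0.11 (percentile 2.26) as deposited and 0.01 (percentile 52.8) adjusted. YUC3 had a ratio of 1.62 (1.17 to 2.25), LAX1 0.543 (0.365 to 0.799), and the transporters ABCB1 and ABCB19 0.653 and 0.624. The log2 ratio of ABCB1 was -0.60, or -0.20 adjusted, and that of ABCB19 -0.66, or -0.24 adjusted.

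Photosystem and light-harvesting genes went both ways. Of 36 photosystem and Calvin cycle genes, 15 had counting intervals above 1 and 10 below. They had a median of 0.05 (percentile 6.51) as deposited and -0.12 (percentile 0.07) adjusted, with the small subunit gene RBCS2B at a ratio of 1.57 (1.43 to 1.73), PSAG at 0.788 (0.765 to 0.813; log2 ratio -0.34, adjusted -0.57) and PSAO at 1.27 (1.2 to 1.34; log2 ratio 0.34, adjusted 0.025). The log2 ratio of RBCS2B was 0.65, or 0.39 adjusted. FNR1 had an interval that included 1. Of 19 light-harvesting genes, 7 had counting intervals above 1 and 4 below, with a median of 0.05 (percentile 18.1), or -0.08 (percentile 5.94) adjusted. LHCA5 was at 2.12 (1.21 to 3.82), LHCB1.1 at 0.821 (0.772 to 0.874) and LHCB4.1 at 1.17 (1.13 to 1.22). Of 20 chlorophyll synthesis genes, none had a counting interval above 1 and 7 had one below, with a median of -0.10 (percentile 3.72), or -0.06 (percentile 14.6) adjusted, and with HEMA1 at 0.779, GUN5 at 0.651, GUN4 at 0.777 and DVR at 0.794. The log2 ratio of GUN5, a long transcript, turned from -0.47 to 0.024 adjusted, and that of HEMA1 went from -0.35 to -0.25. Those of GUN4 and DVR went the other way, from -0.36 to -0.62 and from -0.32 to -0.42. The 22 light signalling genes had -0.11 (percentile 7.00), or -0.09 (percentile 11.5) adjusted, with HFR1 at 0.602 and PHYB at 0.623 (log2 ratio -0.65, adjusted -0.25).

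Of the 29 lists with a percentile, 9 lay outside the central 95% of random lists, and 6 of these did so in the same direction after adjustment. About 1.45 would lie outside if list members varied independently, as in the random lists. Genes of a functional list may vary together, and some lists share members, so 9 against 1.45 does not measure a genotype effect. The senescence and sugar starvation list (11 genes; -0.34, percentile 0.17) and the ethylene list (20 genes; -0.15, percentile 1.73) lay outside as deposited but not adjusted (percentiles 15.4 and 77.6), as did auxin synthesis, transport and perception. Their named members included SAG21 at a ratio of 1.64 (1.4 to 1.93), TPS8 at 0.736 (log2 ratio -0.40, adjusted -0.13), EIN2, the central ethylene signalling gene, at 0.582 (0.528 to 0.640; log2 ratio -0.75, adjusted -0.31) and ERF6 at 0.629 (0.483 to 0.815). Glucosinolate genes (21; -0.07, percentile 4.62) were at -0.15 (percentile 0.84) adjusted, with UGT74B1 at 0.659 and SOT18 at 0.733. Medians of iron (0.17, percentile 97.8 adjusted), oxidative stress (0.20), gibberellin (0.10), brassinosteroid (-0.14), nitrogen (-0.04), shoot meristem and leaf polarity (-0.20), ABA, cold and drought (0.04), circadian clock (-0.01), cytokinin (0.00), heat shock (-0.09) and salicylate genes (0.00) lay within the central 95% as deposited. Adjusted, the medians were 0.14 for iron, 0.029 for oxidative stress, 0.10 for gibberellin, -0.16 for brassinosteroid, 0.046 for nitrogen, 0.019 for shoot meristem and leaf polarity, and 0.029 for ABA, cold and drought. They were 0.039 for circadian clock, -0.10 for cytokinin, -0.013 for heat shock and -0.060 for salicylate genes. Among their members, the iron signalling peptide gene IMA1 had a ratio of 2.76 (1.38 to 5.88), FER1 1.55 (1.45 to 1.66), the brassinosteroid receptor gene BRI1 0.564 (0.518 to 0.614; log2 ratio -0.81, adjusted -0.37), NIA2 0.723 (log2 ratio -0.47, adjusted -0.052) and COR15B 10.3 (1.47 to 448.9), the last from 10 counts against 1. The 12 genes commonly used as references had a median of 0.18 (percentile 68.3), or 0.13 (percentile 95.1) adjusted, and 8 had counting intervals above 1 and none below, with UBQ5 at 1.41 (1.36 to 1.45; log2 ratio 0.49, adjusted 0.16). Of the flowering list, 4 genes were expressed, with SVP at 0.497 (0.227 to 1.03). None of the 4 stomatal lineage and 8 seed storage genes with values here reached a mean RPKM of 1.

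**Figure D4:**
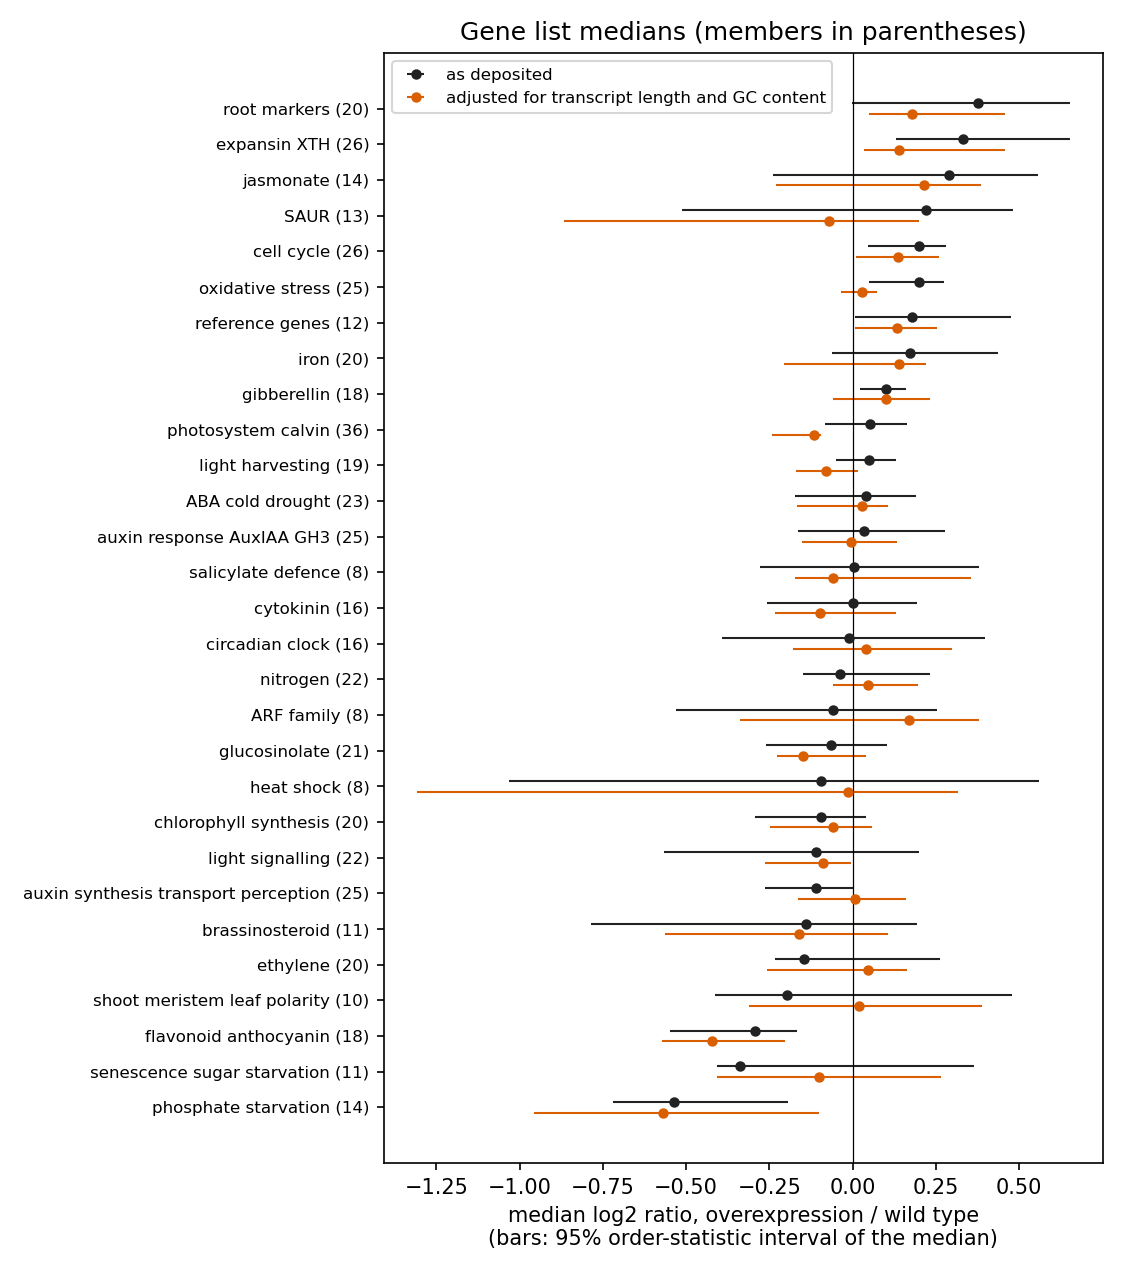
Median log2 ratio of the overexpression over the wild-type library (x axis) for each list with 5 or more expressed members (y axis). Black points are as deposited and orange points adjusted for transcript length and GC content, bars are 95% order-statistic intervals, and phosphate starvation is lowest at -0.54 and -0.57.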

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

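Chloroplast-encoded genes, which the main comparisons left out, took a larger share of the counts in the overexpression library, 0.326% (95% exact binomial interval 0.322 to 0.331), than in the wild-type control, 0.258% (0.254 to 0.261). The share of mitochondrial genes was 0.226% (0.222 to 0.229) against 0.220% (0.216 to 0.223).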

How the results depend on the processing

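No paired analysis was possible because each genotype had 1 library. ARF18 was higher in the overexpression library under each alternative, with log2 ratios between 1.67 (pseudocount of 5 RPKM) and 2.31. The counts of 188 higher and 100 lower genes depended on the pseudocount and thresholds by construction. They were 391 and 249 with a pseudocount of 0.1 RPKM, 23 and 33 with 5 RPKM, 61 and 65 at a mean RPKM of 5 or more, 941 and 711 at 1.5-fold, and 8 and 11 at 4-fold. In the authors' deposited table, whose ratios hold no added pseudocount, 185 transcript models were called lower. With the adjustment for length and GC content, chosen after seeing the data, 79 genes were higher. TMM and median-centred scaling moved the ratios by -0.03 and -0.05 on the log2 scale, and 175 and 166 of the 188 higher genes and all 100 lower genes passed again. With CPM, 115 of the higher and 76 of the lower genes passed again. Of 259 list medians under the alternatives, 255 stayed within the interval of the main value. The 4 others came from the length and GC adjustment: auxin synthesis, transport and perception turned to 0.0056, photosystem and Calvin cycle genes were at -0.12, light-harvesting genes at -0.080 and oxidative stress genes at 0.029. Ethylene turned to 0.046 within its interval, and other lists also changed sign within theirs, such as ARF family (-0.06 to 0.17) and SAUR (0.22 to -0.07). Most alternatives could hardly take a list median out of its interval, so 255 of 259 does not measure stability. Scaling moved ratios little, a pseudocount keeps their signs, and small lists had wide intervals, such as -1.03 to 0.56 for the 8 heat shock genes. Of the single genes named, none at least 2-fold apart changed direction under the alternatives tried for them. Most of these alternatives could not reverse such a gene. A pseudocount keeps the sign of a ratio, and TMM and median-centred scaling moved ratios by only -0.03 and -0.05. At this depth the simulations, which held no trend with transcript length, left 24 higher and 43 lower genes to counting error. In the data the median log2 ratio was 0.36 in the shortest group of genes and -0.36 in the longest. The simulated numbers therefore do not cover genes that passed through this trend together with counting error. Genes of few counts near the threshold are the least certain.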

Other observations

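All tests in this part were chosen after the results were seen. One group was made of genes whose protein carries at least 5 motifs of a serine followed by 3 or more prolines, as extensins do. Some members are other proteins, such as formin-like protein 20 (AT5G07740), TBL32 and the arabinogalactan proteins AGP9 and AGP19. The group was lower in the overexpression library almost throughout: 35 of 36 expressed members had negative log2 ratios and 18 were at least 2-fold lower. Their median was -1.0 (-1.35 to -0.75). EXT3, a structural cell wall extensin, had 22355 counts against 67707, and EXT4 1371 against 3497. The 5 receptor kinase genes of the PERK family among them had negative log2 ratios, from -0.43 in PERK13 (-0.16 adjusted for length and GC content) to -1.21 in PERK10 (-0.97 adjusted), and only PERK10 was 2-fold lower. The one member with a positive ratio was AT3G19430, with 16 counts against 12. The motif was chosen after extensins were seen among the lowest genes, which it includes, so these values describe the group and do not test it.

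For the lower extensin motif genes, adjustment for transcript length and GC content left a median of -0.89 (-1.11 to -0.62). The 17 members with under 5% repeated 25-base words had an adjusted median of -0.67 (-1.06 to -0.43). In these members, neither length and GC content nor repeats within the transcript thus accounted for the whole difference. The values include lowest genes that prompted the motif, with AT3G24480, AT4G18670, LRX3 and AT2G43150 among the 17, so they say nothing beyond these members. The median of -0.67 was smaller in size than -0.89, so a part played by repeats stays open. C-rich sequence stays open. Each member was matched to the 30 other genes nearest in the share of 100-base windows with at least 40% C. Random lists of these had a median of -0.41 (central 95% -0.69 to -0.24) and reached -0.91 at the lowest. Only 10 other genes had at least the members' median share of 36.8%, and their median was -0.62. For the more C-rich members the lists therefore drew on less C-rich genes, so the match was incomplete. A sequence-dependent loss in one library may therefore account for part or all of the difference, and a genotype difference in extensins for any rest, which 1 library per genotype cannot separate.

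For the trend of the log2 ratio with transcript length, GC content is argued against, since within 10 equal groups by GC content the median rho was -0.53 (from -0.58 to -0.26). In the 13926 loci with 1 model that had reads, rho was also -0.53. Such loci can have further annotated models, as ARF18 does, so reads shared between transcript models are not excluded. A length-dependent difference in library making or RNA quality stays open. Of the 26 lists with 10 or more members, 23 (88.5%) had a negative rho within the list, against a mark of 90% set after the results were seen. With a rho of -0.52 across all genes, most lists would have a negative rho under either cause, so this count cannot decide. A library difference cannot be told apart from a genotype difference in long transcripts, because there was 1 library per genotype.

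For the higher root markers, length and GC content are argued against as the whole cause, since the adjusted median kept a percentile of 99.7. The median itself fell from 0.38 to 0.18 with the adjustment, so they may account for a part. A larger share of root tissue in the overexpression library stays open. After the adjustment 3 of the 20 markers, PYK10 (105042 against 130637 counts), SCR and LRX1, had counting intervals wholly below 1 while 6 lay above, but counting error is not the spread between samples, and LRX1 is itself an extensin motif gene.

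The 4 stomatal lineage genes with values here had few counts in both whole-seedling libraries, with the gene TMM at 9 and 5 and SDD1 at 1 and 2, while PYK10, from the root marker list, held 130637 and 105042 counts; these genes, and SCR, were named after their values were seen.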
